A study of Arabidopsis thaliana with 8 samples.

How the data were processed

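Transcript levels were measured by RNA sequencing in 8 libraries of whole Arabidopsis thaliana seedlings of the Col-0 background, 2 libraries for each of 4 groups. Per the labels' protocols, seeds on Murashige and Skoog medium with 1% sucrose stayed at 4 °C for 3 days, received 12 h of white light and then spent 5 days in darkness. Dark wild type (WT dark) was taken from darkness. Wild type (WT red), a phyB mutant and a phyA phyB double mutant (phyAB) were given 1 h of red light at 50 µmol per square metre per second before harvest. The exponent of the length unit in the treatment labels differs from sample to sample and was read as that of a square metre, the unit of the protocol text. Mutant seedlings from darkness were not analysed here, and the mutant alleles are not given in the sources used here. RNA was extracted with a plant kit and treated with DNase, mRNA was taken on oligo(dT) beads, and libraries were made by a standard Illumina procedure, per the labels' protocols.

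Each deposited file holds, for 27416 transcript models with 1 model per locus, a read count and an RPKM value (reads scaled by model length and library total), per the file headers. The authors' reference was TAIR10, per the submitters' processing notes. The aligner, the counting tool, its treatment of reads that map to several places and the strandedness are not given in the sources used here. The deposited read counts are whole numbers with a different total in each library. The deposited RPKM values equal the reads divided by a model length and by the library total: the implied length was a whole number within 0.01 for 100.0% of 24548 models. The counts were therefore analysed, and the RPKM values were used only for this check. Because strand is not known, reads of a gene and of an overlapping or antisense partner cannot be told apart, and near-identical copies such as the LHCB1 genes, the SAUR19 to SAUR24 cluster, the RBCS genes and the TPS-CIN pair may share reads in a way set by the counting tool.

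Locus identifiers were matched to gene symbols of a RefSeq gene table of assembly TAIR10.1, which named 26719 of the 27416 loci. The remaining 697 kept their identifiers. That assembly is not the build named by the submitters, so the table was used for names and for which loci neighbour each other, and no coordinates are given.

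Depth ran from 15926547 reads in phyB replicate 1 to 22116924 in phyB replicate 2. A gene with 0 reads in a library may have had up to 3 reads, which is a floor of 0.136 to 0.188 CPM (counts scaled to the size of the library). Intervals and floors cover counting error only, since the reads carry no molecular identifiers. No read was found in any library for 2868 models.

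Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, genes were kept by filterByExpr with its default minimum count of 10, and a quasi-likelihood model with robust dispersion and 1 coefficient per group was fitted to all 8 libraries. Filtering left 20716 genes. P-values are two-sided and adjusted by the Benjamini-Hochberg method over these genes, and a gene was called at an adjusted p below 0.05 with no limit on the fold. Every adjusted p given for a gene comes from this edgeR quasi-likelihood test. Log2 changes are given with the standard error (SE) of the fit, and CPM values are mean ± SD over 2 libraries. A fold against a group with 0 reads is a lower bound that sets the group at 3 reads over both of its libraries. A fold against a group with 1 to 3 reads carries its 95% counting interval.

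The comparisons were WT red with WT dark, each mutant with WT red, phyAB with phyB, and each mutant with WT dark. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera was repeated with a correlation estimated from the residuals, and fry tested whether a list moved on balance in 1 direction. With an estimated correlation camera tests on the 4 residual degrees of freedom, so p could rise even where the estimate lay below 0.01. There were 18 lists, fixed before the data were examined together with the tests, the alternatives and the rule for named genes: phytochromes, regulators of light signalling, PIF and shade genes, light-harvesting proteins and ELIPs, nuclear photosystem and Rubisco genes, chlorophyll synthesis, flavonoid synthesis, the circadian clock, plastid sigma factors, early auxin response, gibberellin with brassinosteroid and ethylene, cell elongation, ribosome biogenesis, touch and stress, heat shock, seed storage, root cell types, and the stomatal lineage with the shoot apex. They named 298 loci, all found in the files.

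Genes named in the text followed that rule. PHYA, PHYB, HY5, HYH, ELIP1, ELIP2, CHS, PIL1, HFR1, HEMA1, CCA1 and PRR9 are named in the comparisons among dark wild type, red-lit wild type and the mutants whatever their values. Per comparison, the rule added the 6 called nuclear genes with the largest rise and the 6 with the largest fall, among genes whose libraries did not overlap between groups and whose higher group averaged at least 5 CPM. It also added, per list, up to 4 members with the smallest adjusted p and every called member of a list with at most 5 calls.

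The share of the wild-type red-light response found in a mutant was computed over all tested genes as the covariance of the mutant's and the wild type's log2 change from darkness, divided by the covariance of a pair of wild-type changes that shared no library. The 4 ways to assign the wild-type libraries gave its range. Overlaps of calls between comparisons that share the WT red libraries were set beside the overlap of independent lists and beside 20 simulations of unchanged groups.

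The steps were tested on simulated counts drawn from the means of WT dark and the sizes of all 8 libraries, over 20342 genes. The simulated noise was that of counting with some reads in clumps, with no spread between batches of seedlings, so the rates hold for such noise only. Of the genes changed 2-fold, 47 of 50 were called in the right direction, as were 35 of 50 changed 1.5-fold and 50 of 50 changed 4-fold. Of those with a log2 change of 0.32, near the median size of 0.31 of the calls between phyB and WT red, 30 of 50 were called, while 13 of 20142 unchanged genes were called. For simulated shares of 1 and 0.5, the share step returned 1.00 in the phyB and 0.506 in the phyAB libraries, over 20270 genes.

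Alternatives were RLE and upper-quartile scaling, no filter and a filter of 5 CPM in 2 libraries, a limit of 2-fold, DESeq2 1.42.0, a fit of the groups compared alone, the replicate number as a block, and leaving out each library in turn. After the data were seen, a test on the sum of each group's libraries with an assumed biological coefficient of variation (CV) of 0.1 or 0.2 was added. With 2 libraries per group, tests of a single library against its group and other divisions of the libraries into groups were not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.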

Results

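Gene expression was measured in etiolated Arabidopsis seedlings kept in darkness (WT dark) and in wild-type, phyB and phyAB seedlings after 1 h of red light, with 2 libraries in each of the 4 groups. PHYA and PHYB encode phytochromes, the red and far-red photoreceptors of plants, and the series asks how red light and these receptors act in the change from dark to light development. Library totals were 20045824 and 18714337 reads for WT dark, 19760675 and 16326741 for WT red, 15926547 and 22116924 for phyB, and 21699222 and 16619502 for phyAB. The most abundant transcript was BGLU23, a beta-glucosidase of ER bodies, with 1.11% to 1.78% of the reads of a library. Plastid genes held 0.211% to 0.279%.

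The libraries of a group lay close together. In a principal component analysis of log2 CPM, the first component (53.4% of the variance) ran from WT dark through phyAB to WT red and phyB, and the second (24.9%) set phyAB apart from the other groups. The labels call the libraries of a group replicates and do not say whether they came from separate batches of seedlings. Between the libraries of a group, the squared differences in reads were 1.34 to 1.47 times those of pure counting noise, a nearly constant multiple at all depths, and the common biological coefficient of variation was 1.59%. P-values therefore measure only the spread between these libraries, which may be technical, and changes as small as a few percent passed the test. With no mutant seedlings from darkness, a difference between a mutant and the wild type in red light can also have been present before the light.

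PHYA transcripts averaged 831 ± 4.43 CPM in WT dark, 467 ± 5.21 in WT red, 703 ± 0.347 in phyB and 124 ± 0.5001 in phyAB (SD, n = 2). PHYB transcripts averaged 81.0 ± 0.465 CPM in WT dark, 95.6 ± 0.538 in WT red, 63.3 ± 1.41 in phyB and 51.7 ± 1.74 in phyAB. Against WT red, PHYB was lower by −0.59 ± 0.045 (log2 change ± SE, adjusted p = 7.3e-24) in phyB and by −0.88 ± 0.05 (1.2e-37) in phyAB, while PHYA was higher by 0.59 ± 0.015 (4.21e-71) in phyB and lower by −1.92 ± 0.03 (7.29e-101) in phyAB. Both libraries of each mutant went the same way. Transcripts of the mutated genes were thus lower than in WT red but present in the mutant libraries, and with the alleles not given here the levels check the genotype labels only in part.

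**Figure D1:**
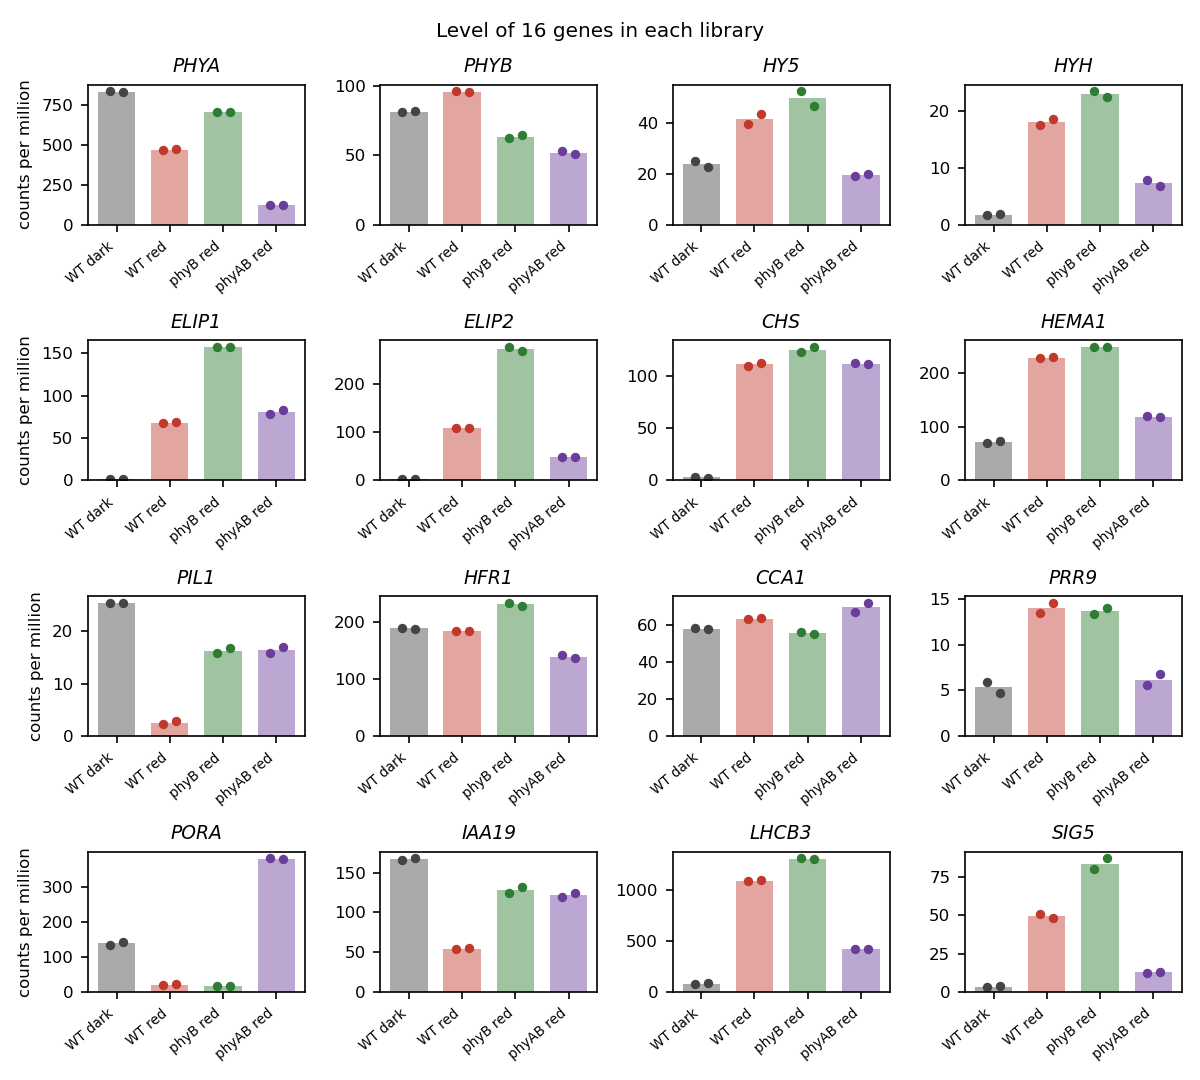
Expression of 16 genes in CPM (vertical axis of each panel), with bars for the group mean and points for its 2 libraries, in WT dark, WT red, phyB and phyAB. LHCB3 averaged 80.5 CPM in WT dark, 1089 in WT red, 1302 in phyB and 421 in phyAB.

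The first comparison, WT red with WT dark, gives the response of wild type to the red light. Genes of the photosynthetic apparatus rose steeply within the hour. LHCB3, a light-harvesting protein of photosystem antennae, rose from 80.5 ± 3.74 to 1089 ± 2.27 CPM, and RCA, which activates Rubisco, rose from 112 ± 4.06 to 1224 ± 5.01 CPM (SD, n = 2). The early light-induced protein genes ELIP1 (log2 change 5.38 ± 0.10, adjusted p = 9.23e-87) and ELIP2 (5.19 ± 0.08, 2.79e-98) and chalcone synthase CHS, the entry enzyme of flavonoid synthesis (5.29 ± 0.08, 8.42e-98), rose from under 3 CPM to 68.2, 109 and 111 CPM. PIL1, a bHLH gene induced in darkness and shade, fell from 25.5 ± 0.00503 to 2.56 ± 0.464 CPM, and the auxin-induced repressor gene IAA19 fell from 167 ± 1.29 to 54.0 ± 0.919 CPM. PORA, the protochlorophyllide oxidoreductase of dark-grown seedlings, fell from 138 ± 4.61 to 19.7 ± 2.09 CPM.

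The lists tied to greening rose almost as a whole. Of 23 light-harvesting and ELIP genes, 22 rose, each at least 2-fold, with a median log2 change over the list of 3.07 (camera adjusted p = 4.32e-58). All 25 photosystem and Rubisco genes rose at least 2-fold (9.4e-66), with RBCS1A up by 1.36 ± 0.01 and PSAF up by 2.84 ± 0.03. In chlorophyll synthesis 20 of 25 genes rose and 2 fell (2.94e-17). The glutamyl-tRNA reductase gene HEMA1 rose by 1.69 ± 0.04. The magnesium chelatase gene CHLH rose by 2.54 ± 0.03 and GUN4 by 3.46 ± 0.06, and the genes that fell were PORA and PORB. PORB was named after its values were seen. All 6 plastid sigma factor genes rose (9.81e-08), from 3.25 ± 0.563 to 49.5 ± 1.601 CPM for SIG5 and from 23.7 ± 2.23 to 75.001 ± 1.303 CPM for SIG1. Of 15 tested flavonoid genes 13 rose and 0 fell (1.62e-10), among them F3H (4.34 ± 0.17), FLS1 (4.62 ± 0.25) and CHIL (3.31 ± 0.16). Of 24 light-signalling regulators 18 rose and 6 fell (1.21e-05). HY5 and its homologue HYH, transcription factors that promote light development, rose by 0.80 ± 0.07 and 3.40 ± 0.16, and SPA1, a partner of the repressor COP1, rose by 1.97 ± 0.04.

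Lists tied to dark growth mostly fell. Of 27 early auxin genes 23 fell and 3 rose (adjusted p = 5.65e-12), with GH3.5 down by −0.95 ± 0.04 and IAA2 by −0.78 ± 0.03 while SAUR14 rose by 1.90 ± 0.10. Of 17 cell-elongation genes 13 fell and 4 rose (1.21e-05): the xyloglucan endotransglucosylase gene XTH19 fell from 218 ± 4.43 to 70.9 ± 2.55 CPM, and the expansin gene EXPA1 rose from 35.8 ± 1.58 to 211 ± 3.43 CPM. Of 17 PIF and shade genes 11 fell and 4 rose, with ATHB-2 down by −1.76 ± 0.08 and PIF4 up by 1.31 ± 0.05. That list passed with the preset correlation (0.000714) but had an adjusted p = 0.0807 with an estimated correlation. HFR1, a bHLH factor that limits shade responses, lay at 188 ± 0.247 and 183 ± 0.162 CPM and was not called (adjusted p = 0.282). Of 18 gibberellin, brassinosteroid and ethylene genes 10 fell and 4 rose (0.00483, adjusted p = 0.083 with an estimated correlation). Among them the ethylene-precursor synthase gene ACS5 fell by −2.35 ± 0.11 and GA2OX1, which inactivates gibberellins, rose by 3.75 ± 0.20.

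Of 20 clock genes 11 rose and 5 fell (adjusted p = 0.0324, and adjusted p = 0.164 with an estimated correlation). PRR9 rose from 5.34 ± 0.874 to 14.0 ± 0.805 CPM and LNK1 from 36.3 ± 0.487 to 127 ± 5.48 CPM, while CCA1 moved by 0.13 ± 0.05 (0.0251), a call lost when any of the 4 libraries was left out. Of 11 tested heat shock genes 8 rose and 1 fell (0.000111), with the chaperone genes HSP70 and HSP90.1 up by 2.39 ± 0.04 and 2.41 ± 0.07. The remaining lists did not pass. Of 5 phytochrome genes 2 rose and 1 fell (0.462), of 13 ribosome biogenesis genes 4 rose and 0 fell (0.462), of 18 touch and stress genes 4 rose and 7 fell (0.909), and of 6 stomatal and apex genes 4 rose and 0 fell (0.113). Of 8 seed storage genes 1, EM6, rose (0.926), and of 13 root genes 2 rose and 5 fell (0.157), or 2 rose and 7 fell adjusted over the list alone. For the phytochrome and the touch and stress lists, the median, the mean and the test differed in sign. Adjusted over the list alone, the counts of all other lists in this comparison were those given.

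The largest rises by rule were those of SDR1, a short-chain dehydrogenase (at least 101.7-fold at a floor of 3 reads over both dark libraries, from 0 reads to 8.11 ± 0.851 CPM), AT1G26761 (151-fold, 95% counting interval 41.5 to 1260), SCPL10 (112-fold), LHCB1.1 (from 4.592 to 475.6 CPM, and sharing near-identical sequence with other LHCB1 genes), FBA5 (96.7-fold) and AT5G48490 (81.5-fold). The largest falls were those of the B-box gene BBX23 (39.1-fold), the locus AT5G53660 named GRF7 (28.9-fold, from 21.6 to 0.748 CPM), AT1G20790 (21.1-fold), CYP96A5 (20.6-fold), AT5G02540 (20.1-fold) and AT5G44260 (15.5-fold).

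In total 9689 of 20716 tested genes were called, 4993 higher and 4696 lower, with 1463 higher and 554 lower by at least 2-fold. Of the lists, light signalling, light harvesting, photosystem and Rubisco, chlorophyll, flavonoid, sigma factor, auxin, cell elongation and heat shock kept an adjusted p between 0.00102 and 0.0268 with an estimated correlation. With an assumed CV of 0.1 on summed libraries the count fell to 3479, and the calls of PHYB, PHYE, CCA1, XTH24, ERF104, NUC1, NOP56, NOP58B and FIB2 were lost. With upper-quartile scaling 42.0% of the calls were higher, against 51.5% here, and HFR1 was called.

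**Figure D2:**
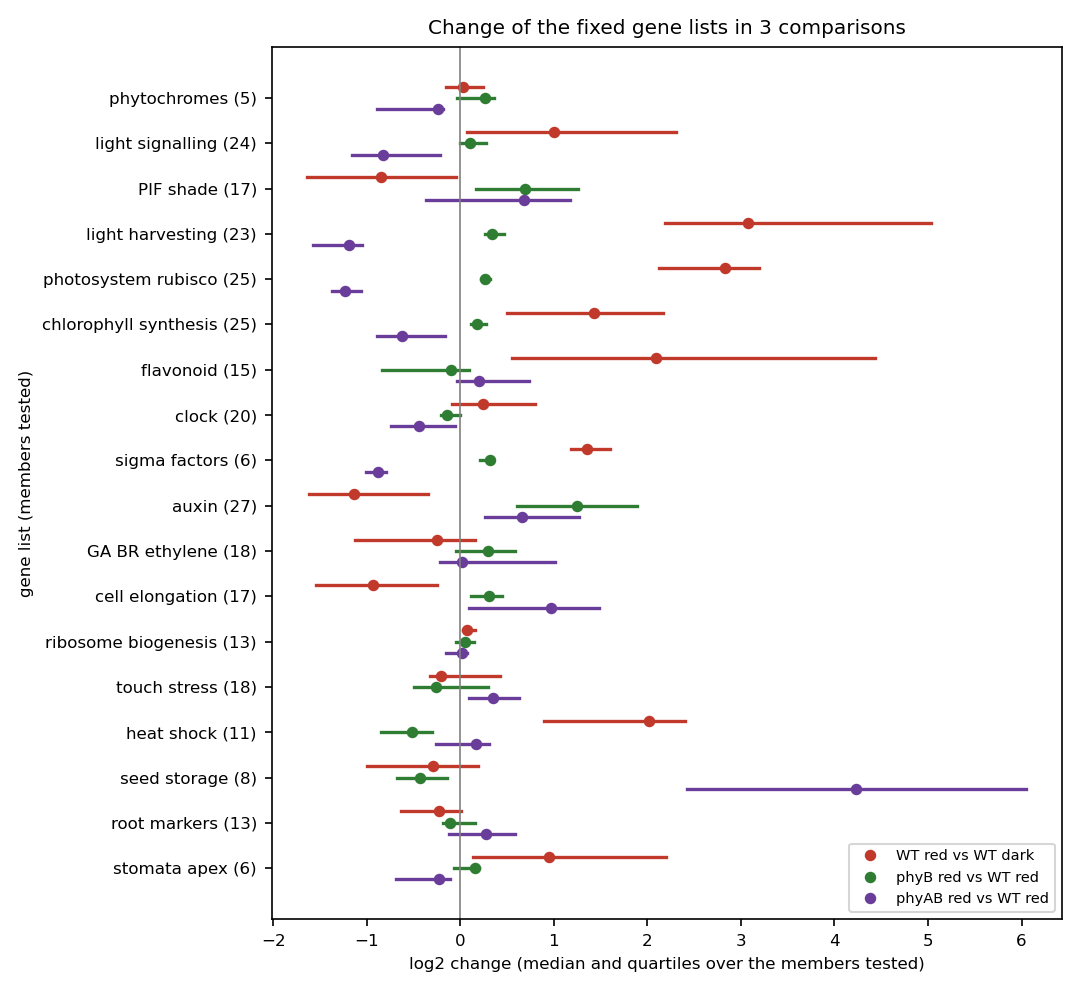
Median log2 change (horizontal axis) of each of the 18 gene lists in WT red against WT dark, phyB against WT red and phyAB against WT red, with lines from the lower to the upper quartile of the members. Light-harvesting genes had medians of 3.07, 0.34 and −1.19 in the 3 comparisons.

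The second comparison, phyB with WT red, asks what the loss of phyB changes in red light. Greening genes were not lower in the mutant. LHCB2.1 averaged 695 ± 8.01 CPM in WT red and 974 ± 7.54 in phyB, and RCA 1224 ± 5.01 and 1714 ± 7.65 CPM (SD, n = 2). ELIP1 was higher by 1.21 ± 0.04 (adjusted p = 9.22e-57) and ELIP2 by 1.32 ± 0.03 (2.04e-71). Auxin and shade genes were the lists with the highest median log2 change, though light-harvesting genes had a smaller list p than shade genes. PIL1 averaged 2.56 ± 0.464 CPM in WT red and 16.3 ± 0.582 in phyB, IAA2 126 ± 2.38 and 293 ± 0.454, and IAA19 54.0 ± 0.919 and 128 ± 5.09.

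All 27 early auxin genes were higher in phyB, 16 of them at least 2-fold (adjusted p = 2.04e-46), with SAUR16 up by 1.89 ± 0.09 and IAA4 by 0.82 ± 0.04. Of 17 PIF and shade genes 13 were higher and 1 lower (2.4e-15), including PAR1 (1.89 ± 0.12) and HAT2 (0.96 ± 0.05). HFR1 was higher by 0.33 ± 0.03 (3.07e-19). Of 17 cell-elongation genes 12 were higher and 3 lower (1.34e-09), with PRE6 up by 1.51 ± 0.06. Of 23 light-harvesting and ELIP genes 21 were higher and 0 lower (1.07e-35, median 0.34), as were all 25 photosystem and Rubisco genes (1.39e-29, median 0.26) and 18 of 25 chlorophyll synthesis genes (2.65e-07, median 0.18), where 19 were higher and 1 lower adjusted over the list alone. HEMA1 was higher by 0.12 ± 0.03 (0.000376) and PORB by 0.45 ± 0.03 (5.46e-26). These lists kept an adjusted p between 0.00136 and 0.012 with an estimated correlation.

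Another group of lists passed only with the preset correlation. For light-signalling (0.00478), heat shock (−0.0155) and root genes (−0.0669) the estimate lay below the preset 0.01, so there the loss does not measure correlation between genes. For sigma factor (0.0752), clock (0.0258) and gibberellin, brassinosteroid and ethylene genes (0.0209) it lay above, and correlation may add to the loss. Of 24 light-signalling regulators 9 were higher and 1 lower, or 10 and 2 adjusted over the list alone (0.0079, adjusted p = 0.0743 with an estimated correlation). RUP1, which represses UV-B signalling, averaged 21.6 ± 0.871 CPM in WT red and 45.006 ± 0.320 in phyB. HY5 and HYH differed by 0.25 ± 0.06 (0.000799) and 0.35 ± 0.10 (0.00283), calls that were lost without WT red replicate 1 (0.0934 and 0.0678) and, for HY5, without phyB replicate 1 (0.0798). Of 6 sigma factor genes 4 were higher (0.0063, adjusted p = 0.103 with an estimated correlation), with SIG5 up by 0.76 ± 0.06. Of 18 gibberellin, brassinosteroid and ethylene genes 11 were higher and 3 lower (0.00141, adjusted p = 0.0664 with an estimated correlation), among them GA20OX1 (0.82 ± 0.08) and ACS8 (2.31 ± 0.30). Of 20 clock genes 1 was higher and 8 lower, or 1 and 9 adjusted over the list alone (0.00925, adjusted p = 0.106 with an estimated correlation). LUX was lower by −0.63 ± 0.06 and CCA1 by −0.19 ± 0.05 (0.00222), while PRR9 lay at 14.0 ± 0.805 and 13.7 ± 0.438 CPM (0.902). Of 11 heat shock genes 6 were lower and 0 higher (0.00471, adjusted p = 0.0664 with an estimated correlation), and of 13 root genes 4 were lower and 2 higher (0.00396, adjusted p = 0.0664 with an estimated correlation), with the root-hair regulator RHD6 at 3.75 ± 0.338 CPM in WT red and 0.962 ± 0.0379 in phyB.

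Of 15 flavonoid genes 4 were higher and 5 lower, or 5 and 6 adjusted over the list alone (0.527). CHS was higher by 0.18 ± 0.04 (6.91e-05), and the anthocyanin genes LDOX and PAP1 were lower by −1.56 ± 0.33 (6.2e-05) and −1.84 ± 0.29 (6.73e-08), the former call being lost without WT red replicate 1 (0.0569). Of 18 touch and stress genes 3 were higher and 8 lower, or 4 and 8 adjusted over the list alone (0.166), of 5 phytochrome genes 3 were higher and 1 lower (0.175), of 13 ribosome biogenesis genes 2 were higher (0.5), of 8 seed storage genes 1 was lower (0.527), and of 6 stomatal and apex genes 1 was lower, or 1 higher and 2 lower adjusted over the list alone (0.89).

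The largest differences by rule were of another kind. AT3G29633 was 89.5-fold higher in phyB (95% counting interval 30.3 to 437), AT3G01345 39.0-fold, AT2G01008 12.1-fold, PIL1 6.68-fold and AT4G13790 6.33-fold, and DML1, a DNA glycosylase that removes methylated cytosine, stood at 73.3 ± 0.784 CPM against 9.44 ± 0.576 in WT red. AT3G55900 had 0 reads in both phyB libraries and was at least 65.4-fold lower at a floor of 3 reads over both, and its neighbour AT3G55910 was 65.7-fold lower (interval 22.1 to 322). AT5G37990 (8.04-fold), AT1G77520 (5.92-fold), the ER chaperone gene BIP3 (5.40-fold) and AT5G04120 (5.04-fold) followed.

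In total 5633 genes were called, 2717 higher and 2916 lower, but 234 higher and 215 lower by at least 2-fold. With RLE scaling 50.7% of the calls were higher, against 48.2% here. With an assumed CV of 0.1 the count fell to 625, and most calls of greening genes in this comparison were lost, among them those of RCA, LHCB2.1, LHCA4, HEMA1, HY5, HYH, CHS, HFR1, CCA1, PHYA and PHYB, while the calls of ELIP1, ELIP2, PIL1, IAA2 and IAA19 were kept. DESeq2 called 3660 genes.

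The third comparison, phyAB with WT red, asks what the loss of both receptors changes in red light. Most greening genes were lower in the double mutant than in WT red, but 22 of 23 light-harvesting and ELIP genes, all 25 photosystem and Rubisco genes and 20 of 25 chlorophyll synthesis genes were higher than in WT dark. LHCB3 averaged 1089 ± 2.27 CPM in WT red, 421 ± 2.29 in phyAB and 80.5 ± 3.74 in WT dark, RCA 1224 ± 5.01, 358 ± 6.78 and 112 ± 4.06, and SIG5 49.5 ± 1.601, 12.7 ± 0.129 and 3.25 ± 0.563 (SD, n = 2). HY5 was lower by −1.09 ± 0.07 (adjusted p = 6.08e-28) and lay at 19.5 ± 0.529 CPM, against 23.9 ± 1.91 in WT dark. CHS did not differ from WT red, at 111 ± 0.740 against 111 ± 2.35 CPM (0.851), and its estimate changed sign without WT red replicate 1 (−0.01). PORA stood at 380 ± 0.595 CPM, above both WT red (19.7 ± 2.09) and WT dark (138 ± 4.61).

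All 25 photosystem and Rubisco genes were lower in phyAB, 20 of them at least 2-fold (adjusted p = 2.0e-56), as were 21 of 23 light-harvesting and ELIP genes with 1 higher (2.56e-42). LHCA4 differed by −1.5968 ± 0.01 and ELIP2 by −1.17 ± 0.04, and the higher gene was ELIP1 (0.24 ± 0.05, 3.08e-06). In chlorophyll synthesis 20 of 25 genes were lower and 2 higher, or 20 and 3 adjusted over the list alone (2.23e-08). HEMA1 differed by −0.94 ± 0.03 and CHLH by −0.82 ± 0.02, and the higher genes were PORA (4.28 ± 0.04) and PORB (1.70 ± 0.03). All 6 sigma factor genes were lower (2.53e-06), as were 19 of 24 light-signalling regulators with 4 higher (9.97e-06), including HYH (−1.28 ± 0.12), SPA1 (−1.36 ± 0.04) and GLK2 (−1.04 ± 0.06). Of 20 clock genes 14 were lower and 4 higher (6.26e-05): PRR9 differed by −1.1974 ± 0.13 and LNK1 by −1.03 ± 0.04, while LHY was higher by 0.82 ± 0.05. CCA1 differed by 0.13 ± 0.05 (0.0197), a call lost without WT red replicate 1 (0.125), WT red replicate 2 (0.0513) or phyAB replicate 2 (0.263). Of 5 phytochrome genes 3, PHYC and the mutated PHYA and PHYB, were lower (0.000676), so the mutated genes weigh on this list test.

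Most growth genes were higher. Of 27 early auxin genes 21 were higher and 5 lower (adjusted p = 8.61e-08), with GH3.3 up by 2.68 ± 0.12 and SAUR14 down by −1.27 ± 0.09. Of 17 cell-elongation genes 13 were higher and 2 lower (3.43e-09). XTH19 averaged 70.9 ± 2.55 CPM in WT red and 339 ± 0.210 in phyAB, against 218 ± 4.43 in WT dark, and the lower genes included EXPA1 (−1.68 ± 0.04). Of 18 touch and stress genes 11 were higher and 2 lower (0.00357), with the calmodulin-like gene TCH3 at 113 ± 1.296 against 43.3 ± 1.33 CPM. The preceding lists kept an adjusted p between 0.00193 and 0.0483 with an estimated correlation. Of 17 PIF and shade genes 12 were higher and 5 lower (0.00502, adjusted p = 0.113 with an estimated correlation). PIL1 was higher by 2.69 ± 0.15, whereas PIF4 (−1.17 ± 0.05), PIF5 (−1.16 ± 0.06) and HFR1 (−0.39 ± 0.03, 3.14e-22) were lower.

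All 8 tested seed storage genes were higher in phyAB, 7 of them at least 2-fold (adjusted p = 3.79e-05, and 0.0284 with an estimated correlation). The cruciferin gene CRU3 averaged 26.8 ± 0.743 CPM in phyAB and 0.183 ± 0.185 in WT red, and CRA1 21.8 ± 0.493 and 0.368 ± 0.432 CPM. The oleosin gene OLEO2 stood at 6.87 ± 1.21 against 1.55 ± 0.289 CPM. CRU3 was also low in WT dark (0.1539 CPM) and phyB (0.1574 CPM), so it may have passed the filter only through phyAB. Such members favour a higher call in every comparison of phyAB, which limits the counts and tests of this list. Lists that did not pass were flavonoid synthesis (9 of 15 higher and 1 lower, 0.0567), root genes (7 of 13 higher and 1 lower, or 7 and 2 adjusted over the list alone, 0.0907), gibberellin, brassinosteroid and ethylene (7 higher and 7 lower of 18, 0.149), heat shock (1 higher and 3 lower of 11, 0.872), ribosome biogenesis (4 of 13 lower, 0.476) and the stomatal lineage and apex (1 of 6 lower, 0.351). Adjusted over the list alone, the counts of the other lists in phyB and phyAB against WT red were those given. Median, mean and test differed in sign for ribosome biogenesis here and for the stomatal and apex list in phyB.

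By rule, the largest differences upward were those of CRU3 (165-fold), the pectin methylesterase gene QRT1 (60.3-fold), CRA1 (57.3-fold), GRF7 (AT5G53660, 31.7-fold), BBX23 (31.4-fold) and GH9B12 (31.1-fold). The largest downward were those of XTH6 (8.06-fold), CP12-2, a regulator of carbon fixation (4.97-fold), the near-identical cineole synthase genes AT3G25820 (4.60-fold) and AT3G25830 (4.44-fold), MSRB6 (4.29-fold) and UBC31 (4.15-fold). In total 9330 genes were called, 4624 higher and 4706 lower, with 837 and 611 by at least 2-fold. With upper-quartile scaling 56.2% of the calls were higher, against 49.6% here, so the majority depended on the scaling. With an assumed CV of 0.1 the count was 2740, and the calls of ELIP1, HFR1, CCA1 and PHYC were among those lost.

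The fourth comparison sets phyAB against phyB and asks what the added loss of phyA changes. RCA averaged 1714 ± 7.65 CPM in phyB and 358 ± 6.78 in phyAB, SIG5 83.9 ± 4.84 and 12.7 ± 0.129, and PORA 17.0 ± 0.282 and 380 ± 0.595 (SD, n = 2). All 23 light-harvesting and ELIP genes (adjusted p = 3.52e-46), all 25 photosystem and Rubisco genes (1.65e-54) and all 6 sigma factor genes (6.0e-07) were lower in phyAB. So were 20 of 25 chlorophyll genes with 2 higher (7.45e-11), 19 of 24 light-signalling regulators with 2 higher (3.3e-07), 19 of 27 auxin genes with 4 higher (7.9e-07) and 4 of 5 phytochrome genes, PHYA and PHYB among them (0.0014). SAUR14 differed by −1.72 ± 0.08 and IAA2 by −0.85 ± 0.03. All 8 seed storage genes (7.65e-05), 8 of 13 root genes (7.65e-05) and 11 of 18 touch and stress genes with 2 lower (0.000899) were higher, for example TIP2-3 (0.91 ± 0.01), WRKY33 (1.18 ± 0.05) and ZAT10 (1.39 ± 0.10). These lists kept an adjusted p between 0.00162 and 0.0478 with an estimated correlation.

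The call was lost with an estimated correlation for PIF and shade genes (3 higher and 9 lower of 17, adjusted p = 0.117), clock (5 higher and 13 lower of 20, adjusted p = 0.101), flavonoid (8 higher and 3 lower of 15, adjusted p = 0.101), cell elongation (10 higher and 6 lower of 17, adjusted p = 0.0961) and heat shock genes (7 of 11 higher, adjusted p = 0.101). Ribosome biogenesis (5 of 13 lower, 0.232), stomatal and apex genes (4 of 6 lower, 0.401) and the gibberellin, brassinosteroid and ethylene list (7 higher and 7 lower of 18, 0.811) did not pass. Adjusted over the list alone, the counts grew by 1 or 2 genes in light signalling (3 higher, 19 lower), chlorophyll (3, 21), flavonoid (10, 3), cell elongation (11, 6), touch and stress (12, 2) and root genes (9, 0). By rule the largest differences upward were those of CRU3 (149-fold), BBX23 (99.3-fold, 95% counting interval 27.1 to 825), AT3G55910 (66.2-fold, interval 22.3 to 324), QRT1 (66.2-fold), CRA1 (65.0-fold) and AT3G55900 (at least 64.5-fold at a floor of 3 reads over both phyB libraries). Those downward were AT3G05950 (150-fold, interval 51.0 to 730), AT3G29633 (95.02-fold, interval 32.2 to 463), CIPK20 (20.5-fold), AT2G01008 (13.1-fold), XTH6 (11.3-fold) and AT3G01345 (11.2-fold). AT3G55900, AT3G55910, AT3G29633, AT2G01008 and AT3G01345 were also among the largest differences between phyB and WT red. Such differences can belong to the phyB line and not to the loss of phyA, and whether phyAB carries the same phyB allele is not given in the sources used here. In total 10392 genes were called, 5404 higher and 4988 lower in phyAB, with 1010 and 901 by at least 2-fold, and with upper-quartile scaling 57.4% of the calls were higher. With an assumed CV of 0.1 the count was 3956.

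The last comparison sets each mutant in red light against dark wild type and asks how much of the wild-type response is found in it. Of the 1463 genes that rose at least 2-fold in wild type, 1240 (84.8%) also did so in phyB and 738 (50.4%) in phyAB, and 622 in both mutants. Of the 554 that fell, 301 (54.3%) also fell at least 2-fold in phyB and 82 (14.8%) in phyAB. The median share of the change was 1.06 for the genes that rose and 0.750 for those that fell in phyB, and 0.574 and 0.210 in phyAB, where 69 of those that fell were called higher than in WT dark. These counts and medians rest on genes selected for a large change in wild type. Both changes also use the same WT dark libraries, so the values can be biased. CHS rose to 125 ± 3.53 CPM in phyB and 111 ± 0.740 in phyAB, and SPA1 from 52.6 ± 0.388 CPM in WT dark to 216 ± 0.0737 in phyB and 80.0 ± 0.661 in phyAB. Over all tested genes the share of the wild-type response was 0.974 in phyB (0.968 to 0.978 over the 4 assignments of libraries) and 0.553 in phyAB (0.550 to 0.555).

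Among genes raised at least 2-fold in wild type, the median share of the log2 change in phyAB was 0.534 for 25 photosystem and Rubisco genes, 0.625 for 22 light-harvesting and ELIP genes, 0.608 for 15 chlorophyll genes, 0.366 for 5 sigma factor genes and 0.333 for 4 clock genes. It was 1.06 for 10 flavonoid genes, 1.08 for 7 heat shock genes, 0.942 for 3 stomatal and apex genes, 0.5405 for 12 light-signalling genes and 0.127 for 3 PIF and shade genes. In phyB the corresponding medians were 1.1, 1.11, 1.09, 1.1956, 0.951, 0.906, 0.689, 1.08, 1.05 and 0.963, in the same order. All of these medians carry the limit of selected genes and shared WT dark libraries given above. Against WT dark, light-harvesting, photosystem and Rubisco, chlorophyll and flavonoid lists were higher in both mutants, with adjusted p between 0.00121 and 0.0182 with an estimated correlation. In phyAB, 17 of 27 auxin genes were lower and 4 higher than in WT dark (0.0358 with an estimated correlation), and all 8 seed storage genes were higher (0.0415 with an estimated correlation). Of 11 heat shock genes 9 were higher and 0 lower in phyAB (adjusted p = 0.0318 with an estimated correlation), and 6 higher and 1 lower in phyB (adjusted p = 0.0806 with an estimated correlation). Of 24 light-signalling regulators 17 were higher and 4 lower in phyB (adjusted p = 0.0191 with an estimated correlation), and 12 higher and 6 lower in phyAB (adjusted p = 0.167 with an estimated correlation). All 6 sigma factor genes were higher in phyB (adjusted p = 0.0256 with an estimated correlation), and 4 in phyAB (adjusted p = 0.0792 with an estimated correlation). The other lists did not pass against WT dark with an estimated correlation. In total 11306 genes were called between phyB and WT dark (1660 higher and 608 lower by at least 2-fold) and 9978 between phyAB and WT dark (1290 and 211). With an assumed CV of 0.1 these counts were 4369 and 2902.

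**Figure D3:**
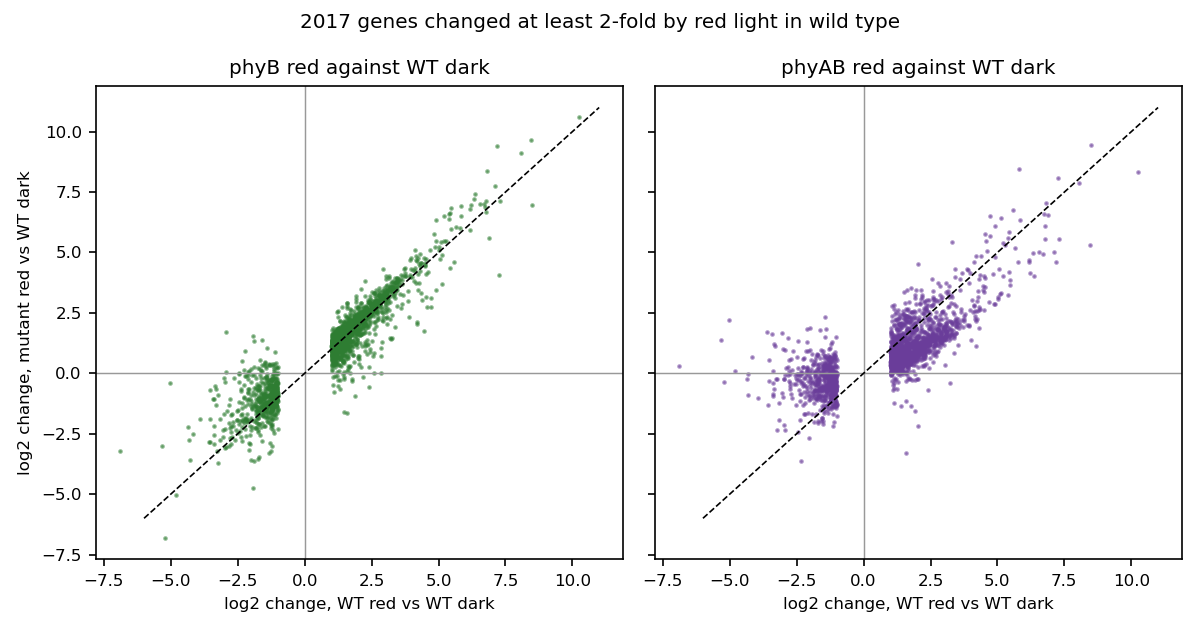
Log2 change of 2017 genes called at least 2-fold in wild type, in WT red against WT dark (horizontal axis) and in each mutant in red light against WT dark (vertical axis), with a dashed line of equality and 1 point per gene. Shares of the wild-type response over all tested genes were 0.974 in phyB and 0.553 in phyAB.

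Calls of the wild-type response and of phyAB against WT red overlapped mainly in opposite directions, whereas in phyB the main direction turned with the limit on the fold. At 2-fold in both comparisons, 482 genes rose in wild type and were lower in phyAB, where independent lists give 43.2, and 297 fell and were higher, where independent lists give 22.4. In phyB these overlaps were 67 (15.2 for independent lists) and 92 (6.26). With no limit on the fold, phyAB gave 2708 and 2195 such genes against 1134 and 1048 for independent lists, and phyB gave 929 and 860 against 703 and 616. In the same direction phyB then gave more, 1082 genes that rose and were higher and 1012 that fell and were lower, against 655 and 661. In 20 simulations of unchanged groups no such overlap exceeded 1. With no gene changed and counting noise only, few calls arise there. The simulations therefore cannot measure what shared libraries add among real calls. These comparisons share the WT red libraries, which were not split because each part would hold 1 library, so part of the excess may come from the shared libraries.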

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

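The tests on one odd library and on neighbouring pairs of genes were chosen only after the results were seen. The test of extra seed genes and the test around PHYB were written before their own outcomes were seen. Both address patterns seen in the results and were not part of the plan fixed before the data were examined.

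In 6 cases the median log2 change of a list against WT dark had the opposite sign in a mutant and in WT red, and the mutant and WT red differed in the list test with an estimated correlation. In phyB this was auxin (0.3432 against −1.1373 in WT red, adjusted p = 0.00136). In phyAB these were phytochromes (−0.2008 against 0.0339, 0.04, a list of 5 genes that holds the mutated PHYA and PHYB), clock (−0.0136 against 0.2448, 0.04), cell elongation (0.2641 against −0.9327, 0.0119), touch and stress (0.2992 against −0.204, 0.0483) and seed storage (3.101 against −0.2861, 0.0284). The changes from WT dark were weaker. With an estimated correlation they passed in the mutant only for seed storage (adjusted p = 0.0415, against 0.138 for auxin, 0.0639 for phytochromes, 0.409 for clock and 0.0792 for both cell elongation and touch and stress), and in WT red only for auxin (0.00604) and cell elongation (0.0193). No list passed on both sides, and for touch and stress in WT red the mean (0.127) and the median differed in sign, so a reversal was not established. Mutant seedlings from darkness were not analysed here, so an effect of genotype before the light and a changed response to it were not separated.

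Seed storage genes in phyAB stood out because all 8 tested members of 11 listed were higher than in WT red, with CRU3 at 26.8 CPM. CRU3 averaged 0.1539 CPM in WT dark, 0.1826 in WT red and 0.1574 in phyB. It may thus have passed the filter only through phyAB, and for such a member a higher level there follows in part from the filter. The rise was not confined to 1 phyAB library, where CRU3 stood at 27.3 and 26.3 CPM. Of the tested members 0 were higher in only 1 phyAB library than in all 6 libraries of the other groups. Both phyAB libraries may come from 1 RNA pool, so their agreement cannot exclude an odd pool. Ungerminated seed or embryo tissue in the phyAB pools is a candidate explanation. Of 24 seed maturation genes outside the list 21 were tested, and 14 of these (66.67%, 95% interval 43.03 to 85.41) were at least 2-fold higher. The interval treats the genes as independent. SESA5, PAP85, ATS1 and AT2G28490, all among the 14, averaged at most 0.4881 CPM in each group other than phyAB. They may therefore have passed the filter only through phyAB, which favours their place among the 14. DOG1 alone was at least 2-fold lower, at low levels (1.15 CPM in WT red and 0.127 in phyAB). Of the 14, OLEO3 did not differ between phyAB and WT dark (0.09, adjusted p = 0.546), so there a missing fall in red light can be the cause. The other 13 were at least 2-fold higher than in WT dark as well. Among these 13, LEA7 (log2 change 1.7074), AT2G42560 (1.6093), AT3G15670 (1.5004) and AT3G17520 (1.1627) also rose at least 2-fold in WT red against WT dark. ABI3 averaged 3.4 CPM in phyB and 3.518 in phyAB. For these genes a level above WT dark does not by itself point to seed tissue. BETA-TIP, not among the 14, was lower in phyAB than in WT dark (3.99 against 20.4 CPM). Slower loss of seed transcripts in this genotype was not tested and stays open.

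Genes with very large differences in phyB stood out because AT3G55900 had 0 reads and AT3G55910 0 and 3 reads in the phyB libraries, while phyAB resembled WT red (log2 change −0.08 and −0.04). A deletion or rearrangement in this phyB line is a candidate explanation. It was tested on 19 genes at least 4-fold lower than in both wild-type groups. Neighbouring pairs beyond the one first noticed, here MRD1 with HEI10 alone, were more frequent than in random draws (one-sided permutation test, p = 0.0165). MRD1 and HEI10 lie on another chromosome and differed from WT red by −2.15 each, so their transcripts remained and this pair does not by itself point to a deletion. The flanking genes AT3G55890 and AT3G55920 were lower in phyB than in WT red by −0.99 and −0.73. Neighbours that respond together stay open, since 120 genes that fell 4-fold in wild type held 2 neighbouring pairs against a random mean of 0.691. For a segment of another background linked to PHYB, genes called 2-fold were 1.334 times as frequent near PHYB as elsewhere (95% interval 0.858 to 2.076, Fisher test, adjusted p = 0.374). This ratio fell short of the limit set beforehand, which by that rule counts against such a segment. The interval reaches past the limit, so the question is left undecided here, a step that the rule did not hold.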

How the results depend on the processing

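The tests with an assumed CV were chosen only after the results were seen. A limit of 2-fold left 2017, 449, 1448, 1911, 2268 and 1501 genes for WT red with WT dark, phyB with WT red, phyAB with WT red, phyAB with phyB, phyB with WT dark and phyAB with WT dark. In that order an assumed CV of 0.1 on summed libraries gave 3479, 625, 2740, 3956, 4369 and 2902, and a CV of 0.2 gave 1259, 95, 578, 986, 1436 and 768. With the 2-fold limit, calls of red light and genotype overlapped in opposite directions for 159 genes in phyB and 779 in phyAB, and in the same direction for 28 and 35. The limit turned the main direction in phyB, where 1789 genes overlapped in opposite directions and 2094 in the same direction without it. DESeq2 called 3660 genes in phyB against WT red. The share of the wild-type response was 0.9564 in phyB and 0.5476 in phyAB over called genes alone, 0.9912 and 0.5453 with the stricter filter, and 0.9660 in phyB with no filter. Fry reversed the direction of seed storage in WT red (5.22e-05) and in phyB against WT dark (0.00171), stomata and apex in phyB against WT red (0.309), gibberellin, brassinosteroid and ethylene in phyB against WT dark (0.0549), and ribosome biogenesis (0.128) and root genes (0.481) in phyAB against WT dark. Upper-quartile scaling reversed seed storage in WT red (0.917). Leaving out 1 library, p ran from 0.912 to 0.999 for seed storage in WT red, from 0.79 to 0.993 for stomata and apex in phyB against WT red and from 0.724 to 0.971 for ribosome biogenesis in phyAB against WT dark. The log2 change ran from −0.0136 to 0.0311 for CHS in phyAB and from −0.0876 to 0.0296 for PRR9 in phyB, both against WT red. None of these reversed lists and genes passed in the edgeR and camera tests of the report. The lone library left in a group was assumed to vary like the other groups. Of 499 results for named genes, 202 calls were lost with the 2-fold limit, 22 with DESeq2, 9 with upper-quartile scaling, 128 with a CV of 0.1 and 255 with a CV of 0.2. Of 108 list results 22 were lost with an estimated correlation, and 1 each with upper-quartile scaling and with no filter. The replicate number as a block changed no call of these genes and lists, and deviations of equally numbered libraries correlated by −0.0036 to 0.027. The cause of these shifts was not tested. A change of pseudocount was not run because the files hold counts, and list tests on summed libraries were not run.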

Other observations

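The tests of gene families, of the spread between replicates and of the shares of lists were chosen only after the results were seen.

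Families were grouped by the names in the gene table. In WT red against WT dark, 12 of 17 3-ketoacyl-CoA synthases, which elongate the fatty acids of waxes, rose and 3 fell (camera adjusted p = 3.54e-05, and 0.64 with an estimated correlation). There, 12 of 14 plastid transcriptionally active genes rose (0.00162, and 0.644) and 12 of 15 proline-rich extensin-like genes fell (0.00123, and 0.644), the second value of each again with an estimated correlation. In phyB against WT red, 15 of 24 tau glutathione S-transferases were lower and 1 higher (0.000232, and 0.355 with an estimated correlation), as were 5 of 8 MLP-like genes with 0 higher (2.86e-10, and 0.355 with an estimated correlation). In phyAB against WT red, 43 of 59 peroxidases were higher and 2 lower (median log2 change 0.4849, 1.13e-15, and 0.16 with an estimated correlation), as were 13 of 15 extensin-like genes (1.3129, 1.23e-11, and 0.394 with an estimated correlation). Of 390 families of 8 to 187 members, 78 results over 4 comparisons passed with the preset correlation and 0 with an estimated correlation. The latter tests on 4 residual degrees of freedom with adjustment over 390 families, so few families could pass. Even chlorophyll a-b binding genes in WT red against WT dark, 7 of 8 up at least 2-fold, had an adjusted p = 0.64 there. The 0 thus does not show that no family moved.

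Libraries of a group may be repeat libraries or runs of 1 RNA pool. Beyond a part proportional to counting noise, the highest upper 95% limit of their CV was 0.4415%. If so, the p-values describe 1 pool per group, and separate batches of seedlings would be the test.

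Flavonoid genes may be raised in phyAB by a route that needs less of these receptors than the photosynthetic genes do. The median share of the wild-type change was 1.0645 over 10 flavonoid genes (1.0379 over the 9 with a read in WT dark) and 0.5613 over 47 light-harvesting and photosystem genes. It was also near 1 for 7 heat shock genes (1.08) and 3 stomatal and apex genes (0.942). This pair of lists was picked for its difference, so a test of the pair alone is not used here. All 10 lists with at least 3 raised genes (106 genes) were tested together, the picked lists among them. Shares differed more between lists than under permutation over genes (permutation test, p = 1e-05, the smallest that 100000 permutations can give). The permutation treats genes as exchangeable, but genes of a list are not independent, so it cannot exclude one distribution of shares. The shares also rest on genes selected for their rise in wild type and on shared WT dark libraries. A higher level in dark phyAB seedlings was not excluded. Dark phyAB seedlings would be the test.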
